A study of Mus musculus with 3 samples.

How the data were processed

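Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in cultured mouse precursor B-cell leukaemia cells driven by Bcr-Abl, a fusion of the Bcr and Abl1 genes that encodes a constitutively active tyrosine kinase. Per the labels' protocols, the cells were grown in medium with 10% serum, cross-linked with formaldehyde, lysed and sonicated, and the libraries were made with an Illumina kit. There were 3 samples: 1 immunoprecipitation of histone H3 acetylated at lysine 27 (H3K27ac), 1 of histone H3 trimethylated at lysine 4 (H3K4me3) and 1 with control immunoglobulin (IgG). The labels state 11% formaldehyde, and whether this is the final or the stock concentration is not given in the sources used here. Groups were taken from the sample titles.

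Per the submitters' processing notes, peaks were called with MACS, a program that finds regions enriched in a ChIP library over a control, and positions refer to the mouse build mm9. The MACS version, the aligner, the read filters and the number of reads are not given in the sources used here. The deposited data are 1 peak list per mark, each with the chromosome, start, end and a score for every peak. Each list was called by the authors on 1 library, so no replicates were pooled. The deposited score is the authors' own value for each peak; neither a header nor a label defines it. The lowest score was 50.01 in both lists, and 6863 H3K27ac and 9042 H3K4me3 scores were exactly 3100, so many high-scoring peaks are tied. This value is called the ceiling here, although 243 H3K27ac and 75 H3K4me3 scores exceed it. Whether peaks above it are stronger than peaks tied at it is not known. Scores were used only within a list, to rank or filter peaks, to give medians and shares at the ceiling and, in 1 alternative, to rank stitched regions by summed score. A peak list from a deeper or more efficient library holds more weak peaks, so differences in length between the lists can come from depth as well as from chromatin. The IgG library had no peak list of its own here and its signal was not analysed. Positions are given counted from 1, on mm9.

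No annotation or sequence of mm9 was used here. The reference table at hand follows another assembly, GRCm38.p6, and the deposited chromosome 1 peaks reach position 197068663. For that reason peaks were not assigned to genes or start sites, and the planned analyses of promoters, fixed gene lists (B lineage, pre-B receptor and recombination, kinase signalling, glucocorticoid response, apoptosis, other blood lineages, developmental, tissue-specific, ubiquitous and cell-cycle genes), distal peaks, motifs and CpG content were not made. Only the order of genes along 3 chromosomes was taken from the table, for a hypothesis in the closing section. Peaks are named by position, under the rule set for this case before the data were examined: the 10 widest and the 10 highest-scoring peaks of each mark. The definitions of stitched regions and broad domains were also planned, but those named by position were singled out after their values were seen. The same holds for peaks at the score ceiling without the other mark and for 1 Mb bins, which were not planned.

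Peaks of the 2 marks were called overlapping when they shared at least 1 bp (bedtools 2.31.1). Percentages carry exact 95% binomial (Clopper-Pearson) intervals and medians carry distribution-free 95% intervals from order statistics. These intervals treat peaks as independent and cover counting error only. With 1 library per mark there is no replicate error, no test between samples was made and no p-value is given. As a background, the peaks of 1 mark were placed at random 100 times with their widths and chromosomes kept, between the first and last peak of each chromosome; a second background, added after the data were seen, moved all peaks by 100 kb to either side, which keeps their local crowding. H3K27ac peaks placed at random were also stitched, a check added after the data were seen. H3K27ac peaks within 12500 bp were stitched and ranked by summed peak length, and long regions were those above the point where the scaled rank curve has a slope of 1. This ranking is by length, since read density was not at hand. H3K4me3 peaks within 1000 bp were joined, and the widest 5% of the joined domains were called broad. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

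The scripts were tested on simulated data. With 9810 simulated peaks, of which 81.5% were placed on H3K27ac peaks, the overlap was recovered with 0 wrong calls. Independently placed H3K4me3 peaks overlapped 2.93% of the 29468 H3K27ac peaks, against a mean of 3.09% in random placements. The rank curve returned 504 long regions where 500 of 10000 had been simulated. The simulated cases were clear-cut, and the independent peaks were placed by the same steps as the random placements. These tests therefore check only that the code runs as written. Alternatives covered the score threshold, the overlap that counts, lists of the same length, joining of neighbouring peaks, the chromosomes used, the stitching distance, the ranking and the joining distance.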

Results

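The 2 peak lists describe untreated mouse precursor B-cell acute lymphoblastic leukaemia cells, 1 library per mark. H3K27ac is found at active promoters and enhancers, and H3K4me3 at promoters. The H3K27ac list held 29468 peaks covering 65.8 Mb, and the H3K4me3 list held 18142 peaks covering 35.7 Mb. Median peak width was 1782 bp (quartiles 1020 and 2720 bp) for H3K27ac and 1807 bp (quartiles 1008 and 2585 bp) for H3K4me3, but H3K27ac had 307 peaks wider than 10 kb and H3K4me3 had 9. Scores of 3100 or more, at or above the ceiling, were given to 24.1% of H3K27ac peaks and 50.3% of H3K4me3 peaks, shares that are not comparable between the libraries. Sequencing depth is unknown, and no replicates exist for either mark, so none of the values below has a replicate error.

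The first comparison asked where the 2 marks lie together. Most H3K4me3 peaks carried H3K27ac, while H3K27ac was also present at many positions without H3K4me3. Of the H3K4me3 peaks, 15617 (86.1%, interval 85.6 to 86.6%) overlapped an H3K27ac peak. Of the H3K27ac peaks, 15409 (52.3%, interval 51.7 to 52.9%) overlapped an H3K4me3 peak, which left 14059 with H3K27ac alone. The marks shared 30.1 Mb, equal to 84.3% of the H3K4me3 length and 45.7% of the H3K27ac length. Random placement gave a mean overlap of 4.93% for H3K4me3 peaks (range 4.54 to 5.37%) and 3.09% for H3K27ac peaks (range 2.83 to 3.32%), so the observed overlaps were 17.5 and 16.9 times higher. Against peaks moved by 100 kb, which overlapped 10.7 and 10.8% of H3K4me3 peaks and 6.98 and 6.85% of H3K27ac peaks to the left and to the right, the observed overlaps were 8.01 and 7.56 times higher. With the H3K27ac list cut to its 18142 highest-scoring peaks, so that both lists had the same length, the overlaps were 75.3% of H3K4me3 peaks and 72.3% of H3K27ac peaks. The number of H3K4me3 peaks without H3K27ac thus depended on the length of the H3K27ac list: it was 2525 with the full list and 4489 with the shortened one. The H3K27ac-only class depended on that length too, since the share of H3K27ac peaks with H3K4me3 rose from 52.3 to 72.3% when the lowest-scoring peaks were removed.

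Co-occurrence rose with peak score in both lists. Among H3K4me3 peaks scoring 50 to 100, 57.6% (interval 55.5 to 59.7%) overlapped H3K27ac, compared with 99.8% (interval 99.7 to 99.9%) of the 9117 peaks at or above the ceiling. Among H3K27ac peaks the share with H3K4me3 was 15.4% (interval 14.4 to 16.4%) at scores of 50 to 100 and 90.8% (interval 90.1 to 91.5%) in the 7106 peaks at or above the ceiling. The intervals of the lowest and highest score class did not overlap for either mark. A total of 652 H3K27ac peaks at or above the ceiling lay outside H3K4me3, as did 14 H3K4me3 peaks outside H3K27ac.

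**Figure D1:**
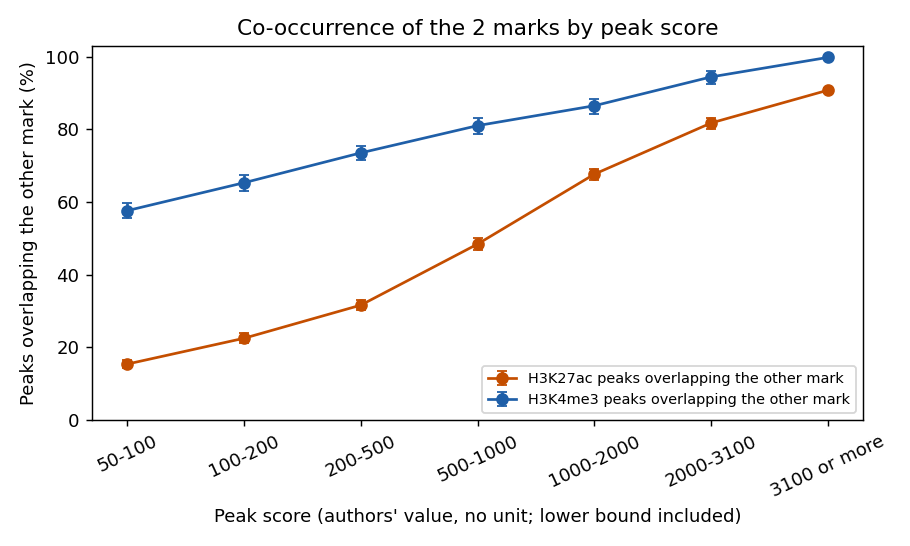
Percentage of H3K27ac peaks (orange) and H3K4me3 peaks (blue) that overlap a peak of the other mark, in 7 classes of the authors' peak score; points are percentages and bars are exact 95% binomial intervals. The H3K4me3 curve goes from 57.6% to 99.8% and the H3K27ac curve from 15.4% to 90.8%.

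Peaks that carried both marks were wider and scored higher than peaks with 1 mark. H3K27ac peaks with H3K4me3 had a median width of 2245 bp (interval 2223 to 2269 bp), 1.79 times the 1252 bp (interval 1234 to 1272 bp) of H3K27ac peaks without it. H3K4me3 peaks with H3K27ac had a median width of 2009 bp (interval 1991 to 2028 bp), 2.63 times the 763 bp (interval 746 to 779 bp) of those without. Median scores were 2414 and 188 for H3K27ac peaks with and without H3K4me3, and 3100 (the ceiling) and 137 for H3K4me3 peaks with and without H3K27ac. Each of the 1057 H3K4me3 peaks of 4000 bp or more overlapped H3K27ac, whereas 726 of the 3202 H3K27ac peaks of 4000 bp or more had no H3K4me3. A wider peak has a greater chance of touching another at random, which these comparisons do not remove. Limiting both lists to scores of at least 100 gave median widths with and without the other mark of 2324 and 1715 bp for H3K27ac. For H3K4me3 they were 2147 and 965 bp. The H3K27ac difference in width was thus smaller without the weakest peaks. The median score of the peaks without the other mark became 384 for H3K27ac and 273 for H3K4me3, a rise that removing low scores must give.

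**Figure D2:**
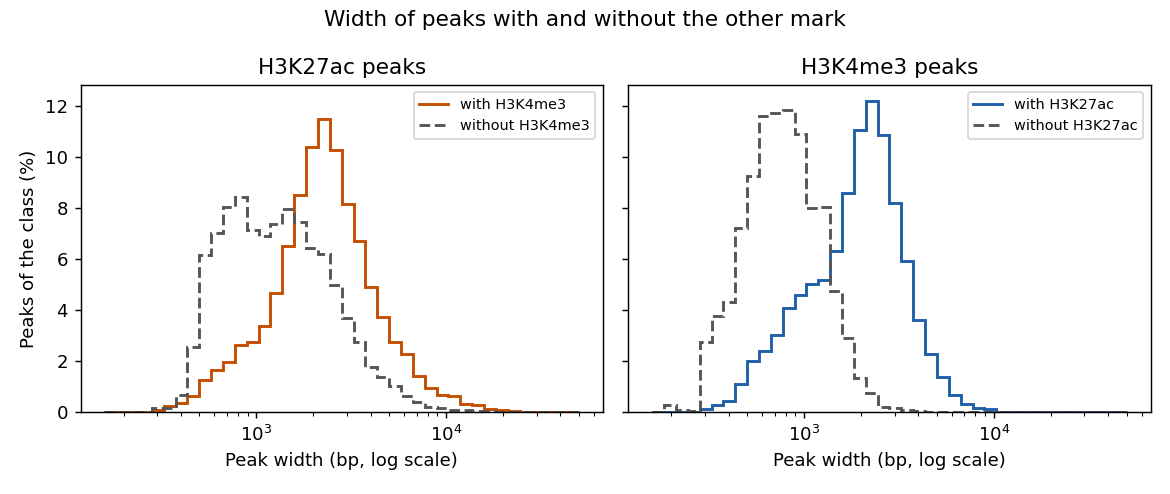
Distribution of peak width (bp, log scale) for H3K27ac peaks (left) and H3K4me3 peaks (right), as the percentage of each class per width bin; solid lines are peaks that overlap the other mark and dashed lines are peaks that do not. The medians are 2245 and 1252 bp on the left, and 2009 and 763 bp on the right.

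In 13911 cases 1 H3K4me3 peak met 1 H3K27ac peak and no other. Neither mark was the wider by much across these pairs. The median widths were 2250 bp for H3K27ac and 2020 bp for H3K4me3. The median signed difference within a pair, H3K27ac minus H3K4me3, was 37 bp (interval 23 to 50 bp). Differences of opposite sign cancel in this median, so it does not measure how alike the widths of a pair were. H3K27ac was the wider mark in 52.4% of pairs (interval 51.5 to 53.2%). The H3K4me3 peak lay inside the H3K27ac peak in 36.9% of pairs, and the reverse held in 29.0%. There were 466 H3K4me3 peaks that met 2 or more H3K27ac peaks and 589 H3K27ac peaks that met 2 or more H3K4me3 peaks. The pairs leave these peaks out, among them the widest H3K27ac peak of the list, so the comparison of widths does not cover them.

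H3K27ac peaks without H3K4me3 lay nearer to H3K4me3 peaks than random positions did. Their median distance to the nearest H3K4me3 peak was 17.1 kb (interval 16.5 to 17.7 kb), against 107 kb for random positions. Of these 14059 peaks, 37.3% (interval 36.5 to 38.1%) lay within 10 kb of H3K4me3, against a mean of 11.6% (range 10.8 to 12.3%) in random placements, and 12.8% lay more than 100 kb away. H3K4me3 peaks without H3K27ac were at a median of 29.9 kb (interval 27.7 to 31.8 kb) from the nearest H3K27ac peak. Within 10 kb of H3K27ac were 25.5% of them, against a mean of 14.7% and a highest value of 16.9% in random placements. These placements do not keep the local crowding of peaks, and the move by 100 kb was not applied to distances. Closeness to the other mark is therefore not separated from crowding of peaks in general.

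The widest H3K27ac peak covered 39.7 kb on chromosome 4 (44888183 to 44927847). The other members of the 10 widest were 36.5 kb on chromosome 15 (63466548 to 63503008), 35.4 kb on chromosome 16 (95621577 to 95656958), 33.8 kb on chromosome 15 (63430698 to 63464458), 32.9 kb on chromosome 7 (139899978 to 139932833), 32.4 kb on chromosome 16 (19002499 to 19034876), 28.6 kb on chromosome 13 (23829181 to 23857734), 27.3 kb on chromosome 3 (53772583 to 53799884), 26.0 kb on chromosome 7 (108598801 to 108624788) and 25.1 kb on chromosome 17 (46164219 to 46189357). All 10 scored 3100, and 8 of them overlapped H3K4me3. The 2 without it were the 33.8 kb peak on chromosome 15 and the 32.4 kb peak on chromosome 16. On chromosome 15 that peak was followed by the 36.5 kb peak, which did carry H3K4me3.

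The widest H3K4me3 peak, 15.3 kb, also lay on chromosome 4 (44711833 to 44727101), 161 kb from the widest H3K27ac peak. An H3K27ac peak of 15290 bp (44711966 to 44727255) covered almost the same positions. The next widest H3K4me3 peaks were 13.6 kb on chromosome 16 (16859497 to 16873138), 11.8 kb on chromosome 11 (11584782 to 11596584), 11.7 kb on chromosome 4 (149069523 to 149081259) and 10.5 kb on chromosome 8 (81147852 to 81158332). The remaining 5 measured between 9.81 and 10.3 kb and lay on chromosomes 3, 9, 19, 11 and 7. All 10 overlapped H3K27ac.

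**Figure D3:**
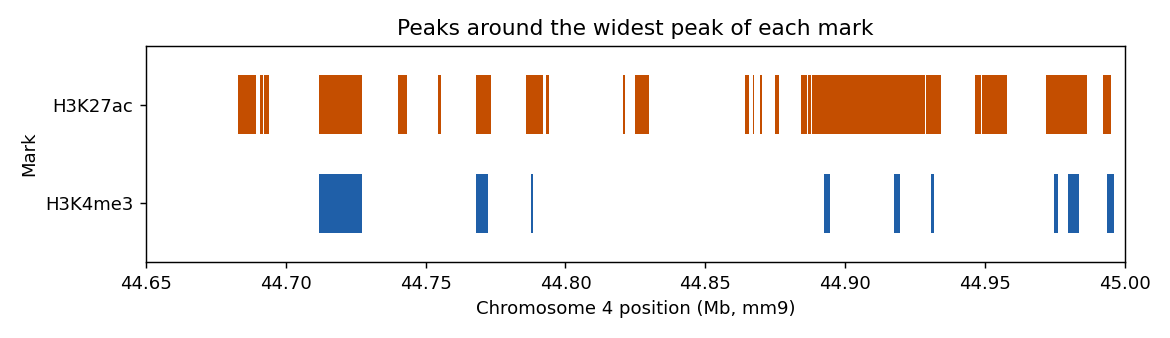
Peaks of H3K27ac (orange, upper row) and H3K4me3 (blue, lower row) in the part of chromosome 4 that holds the widest peak of each mark; boxes span the deposited start and end of each peak (Mb, mm9). The window holds 28 H3K27ac and 9 H3K4me3 peaks, and the 15.3 kb H3K4me3 peak and the 39.7 kb H3K27ac peak lie 161 kb apart.

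The 10 highest-scoring peaks of each mark were not among its 10 widest. For H3K27ac they measured 1777 to 4146 bp, scored 3230 to 3233 and all overlapped H3K4me3. At the top, 7 peaks were tied at 3233, among them a peak on chromosome 1 (168308640 to 168311103) and a peak on the X chromosome (34666223 to 34668422). For H3K4me3 they measured 1441 to 3127 bp and scored 3207 to 3233, led by a peak on chromosome 15 (101146122 to 101149248). Of these 10 H3K4me3 peaks, 8 overlapped H3K27ac. The other 2 were on chromosome 5 (130370963 to 130372462), 7.02 kb from the nearest H3K27ac peak, and on chromosome 10 (62187968 to 62189408), 9.89 kb from it. Only 243 H3K27ac and 75 H3K4me3 scores exceeded the ceiling, while 6863 and 9042 were tied at it. The score is not defined, so peaks above the ceiling cannot be called stronger than those tied at it. This ranking therefore says nothing certain about strength.

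The 14 H3K4me3 peaks at or above the ceiling without H3K27ac had the highest scores among positions of H3K4me3 alone. The widest were 3833 bp on chromosome 13 (78337044 to 78340876), which ended 0.97 kb from an H3K27ac peak, 3287 bp on chromosome 7 (128534903 to 128538189), 29.0 kb from one, and 3041 bp on chromosome 13 (21250770 to 21253810), 4.94 kb from one. The most isolated were on chromosome 14 (46703669 to 46704732), 425 kb from the nearest H3K27ac peak, and on chromosome 15 (89421507 to 89422970), 114 kb from it.

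H3K27ac peaks lay closer together than random placement gave. Stitching gave 16134 regions, of which 1032 (6.40%) were long, with more than 11.2 kb of summed peak length. The long regions held 21.0% of all H3K27ac peaks and 30.9% of the summed peak length, with a median of 5 peaks and 16.1 kb per region, against 1 peak and 2.32 kb in the other regions, a contrast set by the selection on length. When the H3K27ac peaks were placed at random, stitching gave a mean of 24692 regions (range 24542 to 24871), of which 348 (range 326 to 380) exceeded the same limit and held 2.44% of the peaks and 8.10% of the summed length. Some called peaks nearly touch: on chromosome 4 a peak ended at 44956660 and the next began at 44956672. Random placement separates such neighbours, so the contrast and the peak numbers depend in part on how the peaks were divided when called. The region with the largest summed length, 109 kb in 36 peaks, lay on chromosome 16 (93105660 to 93309701) and held 2 H3K4me3 peaks. It was followed by 86.9 kb on chromosome 15 (63428244 to 63529636, 3 H3K4me3 peaks), 86.5 kb on chromosome 10 (59610616 to 59754608, 9 H3K4me3 peaks) and 73.2 kb on chromosome 11 (118006565 to 118122703, 11 H3K4me3 peaks). The tenth region, 63.7 kb on chromosome 4 (44864372 to 44957844), contained the widest single H3K27ac peak.

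Of the long regions, 969 (93.9%, interval 92.3 to 95.3%) held H3K4me3, against 68.1% (interval 67.3 to 68.8%) of the other regions. Random placement gave 20.2% for the long regions and 4.81% for the others, so part of the difference follows from their length. The 63 long regions without H3K4me3 were led by 62.0 kb in 12 peaks on chromosome 16 (19002499 to 19089169), 44.1 kb in 16 peaks on chromosome 12 (116685411 to 116772535), 39.9 kb in 16 peaks on chromosome 14 (94907708 to 94966696), 36.8 kb in 10 peaks on chromosome 16 (81324353 to 81372566) and 33.7 kb in 10 peaks on chromosome 6 (69327331 to 69390800).

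Broad H3K4me3 domains coincided with the long H3K27ac regions more often than other H3K4me3 domains did. Joining gave 17471 H3K4me3 domains, and the widest 5% were 873 domains of at least 4435 bp (median 5260 bp). All but 1 of these overlapped H3K27ac (872, 99.9%), against 85.6% of the rest. Long H3K27ac regions contained or touched 370 of the broad domains (42.4%, interval 39.1 to 45.7%) and 2369 of the 16598 others (14.3%, interval 13.7 to 14.8%). Random placement gave 2.04% and 1.74%. Part of this difference follows from width, since H3K27ac under a broad domain itself adds to the length of its region. Without the H3K27ac length under each domain, 24.6% of the broad domains (interval 21.8 to 27.6%) and 1991 of the 16598 others (interval 11.5 to 12.5%) lay in regions above the same limit. The 10 widest domains measured 11.4 to 15.9 kb, and all 10 lay in long regions by the first count and 3 by the second. They were led by a domain of 4 peaks on chromosome 15 (97647192 to 97663057), the 15.3 kb peak on chromosome 4 and a 13.7 kb domain of 2 peaks on chromosome 3 (87940803 to 87954504).

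Chromosomes differed in peak density and in the share of H3K27ac without H3K4me3. Chromosome 11 was the densest, with 17.7 H3K27ac and 11.7 H3K4me3 peaks per Mb, followed by chromosome 19 with 16.4 and 10.5. The X chromosome was the sparsest of the autosomes and X, with 4.72 and 3.25 peaks per Mb, and the Y chromosome had 3 peaks of each mark. The share of H3K27ac peaks without H3K4me3 was 57.7% on chromosome 12 (interval 55.1 to 60.3%), 53.9% there without the domain described next (interval 51.1 to 56.6%), 55.0% on chromosome 16 (interval 52.0 to 58.0%) and lowest on chromosome 7 (39.8%, interval 37.5 to 42.1%). The longest stretch with neither mark was 7.65 Mb on chromosome 7 (39057408 to 46704226). Contigs that mm9 does not place held 67 H3K27ac and 64 H3K4me3 peaks, of which 47 and 46 overlapped the other mark.

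A pair of domains, on chromosomes 6 and 12, was set apart by H3K27ac peaks without H3K4me3. The genome was divided into 2647 bins of 1 Mb, with a median of 3 such peaks per bin and a 99th percentile of 27. Only 4 bins held 50 or more, a limit set after the data were seen, and they formed 2 neighbouring pairs. On chromosome 6 (68000001 to 70000000) 135 of 153 H3K27ac peaks (88.2%) had no H3K4me3, and on chromosome 12 (115000001 to 117000000) 133 of 145 (91.7%) had none. These domains held 19 and 13 H3K4me3 peaks. The next bin, on chromosome 16 (93000001 to 94000000), held 46 and contained the largest stitched region. With scores of at least 100 in both lists, each of the 2 domains held 99 H3K27ac peaks without H3K4me3, of which 94 on chromosome 6 and 96 on chromosome 12 were among those counted above, and leaving the domains out gave an H3K27ac overlap with H3K4me3 of 52.7%.

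**Figure D4:**
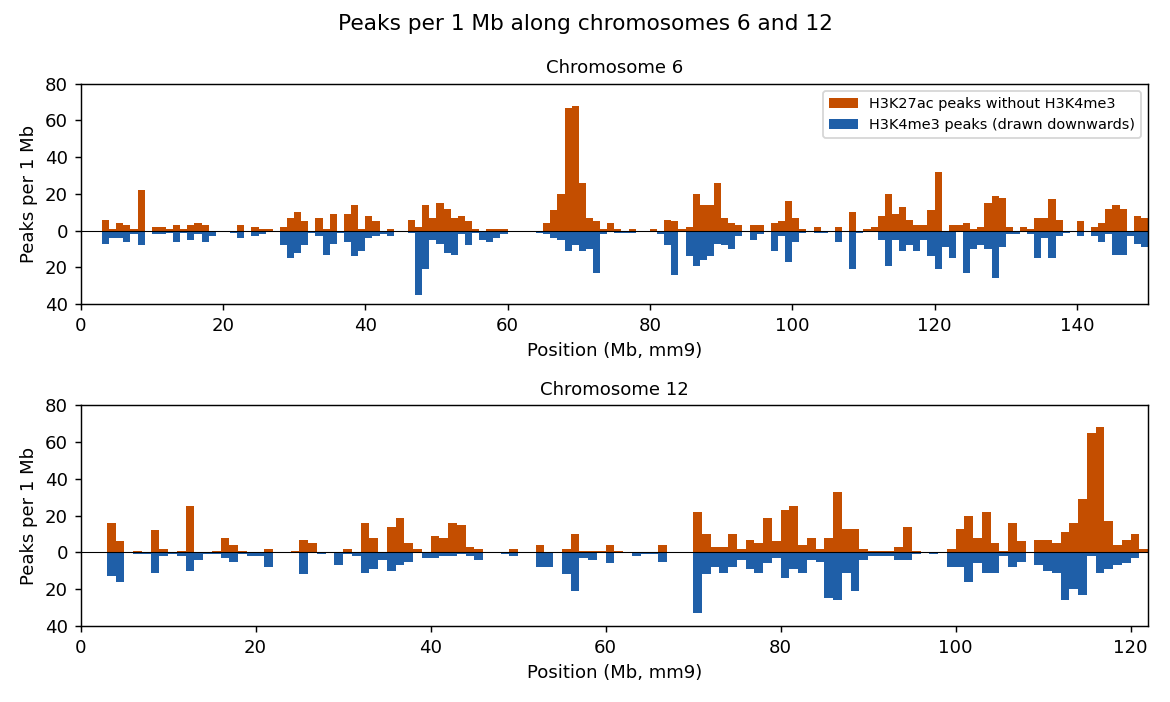
Number of H3K27ac peaks without H3K4me3 (orange, upwards) and of all H3K4me3 peaks (blue, drawn downwards) in 1 Mb bins along chromosomes 6 and 12 (position in Mb, mm9). The bins from 68 to 70 Mb on chromosome 6 and from 115 to 117 Mb on chromosome 12 hold 135 and 133 H3K27ac peaks without H3K4me3.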

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

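Of 45 alternative values, 23 stayed within the interval of the reported value (for counts and limits of width, within 1.5 times) and 22 moved outside it. No reversal was recorded, but most of these values are single percentages, medians or counts with no direction to reverse. The percentage of H3K27ac peaks overlapping H3K4me3 was 52.3% and became 56.4% with scores of at least 100, 54.2% when a distance of up to 1000 bp counted, 57.4% with neighbouring peaks joined first and 72.3% with lists of the same length. The percentage of H3K4me3 peaks overlapping H3K27ac was 86.1% and became 86.7% with scores of at least 100 and 75.3% with lists of the same length. A shorter H3K27ac list gives fewer peaks to meet. With lists of the same length and most overlaps between 1 peak of each mark, the percentages of 72.3 and 75.3% had to be close. Their closeness therefore does not bear on the difference between the marks. Requiring 50% of the shorter peak, or autosomes only, moved neither percentage beyond its interval. With scores of at least 100, median widths of peaks with and without the other mark became 2324 and 1715 bp for H3K27ac and 2147 and 965 bp for H3K4me3. Median scores became 2754 and 384 for H3K27ac and 273 for H3K4me3 without H3K27ac, as follows from removing low scores. With neighbouring peaks joined, the H3K27ac widths became 2357 and 1498 bp and the scores 2571 and 232, and the H3K4me3 width with H3K27ac became 2073 bp. The number of long stitched regions ranged from 926 to 1146 over its alternatives and that of broad domains from 777 to 907. Leaving out H3K27ac under the broad domains lowered the share of broad domains in long regions from 42.4% to 24.6%, by fewer bases counted. Leaving out that length or the 2 domains, and the score threshold for stitched regions, broad domains and the 2 domains, were chosen after the data were seen. The alternatives that need gene starts or sequence, including stitching without peaks near starts, were not run. No paired analysis was possible because each group has 1 sample. Unknown depth limits what an absent peak means.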

Other observations

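The hypotheses below were formed after the peak positions had been seen, and the values of their tests were computed afterwards. Pre-B cells rearrange the immunoglobulin genes, which in the mouse lie on chromosomes 12 (heavy chain), 6 (kappa light chain) and 16 (lambda light chain); the variable segments of the heavy and kappa chains form long clusters. The domains of H3K27ac without H3K4me3 on chromosomes 6 and 12 may be the kappa and heavy chain variable clusters, which was tested by gene order because positions could not be compared between builds. In the GRCm38.p6 gene table, 39.1% of the protein-coding genes of chromosome 6 precede the 162 kappa segments and 97.8% of those of chromosome 12 precede the 183 heavy chain segments, while 35.1% and 94.6% of the H3K4me3 peaks precede the domains. The larger difference was 3.95 points, within the 10 points set before it was computed, a criterion that 23.3% and 7.38% of the 1 Mb bins of the 2 chromosomes also meet, so the identity stays a hypothesis. Weak peaks near the calling threshold were another candidate cause. With scores of at least 100, the 4 bins of the domains still held 44 to 55 H3K27ac-only peaks each, against at most 35 in any other bin. Of the H3K27ac-only peaks, 29.1% scored under 100 in the domains and 31.5% elsewhere. The crowding was thus not limited to peaks scoring under 100. The bins had been picked for their counts of these same peaks, so their staying highest does not exclude weak peaks as a cause. The median score of all H3K27ac-only peaks over both domains was 279 (interval 202 to 408), against 187 (interval 182 to 193) elsewhere. The intervals of the single domains (174 to 471 on chromosome 6 and 169 to 449 on chromosome 12) include 187. Both medians lay below the 710 of the whole H3K27ac list. Reads shared between near-identical segments and extra DNA copies stay open, since reads and IgG signal were not analysed.

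The stitched H3K27ac region without H3K4me3 that had the largest summed peak length, on chromosome 16 (19002499 to 19089169), may in the same way be the lambda locus. Before it lay 24.3% of the H3K4me3 peaks of the chromosome, and 25.5% of the protein-coding genes precede the 12 lambda segments (variable, joining and constant together), a difference of 1.17 points; 9.09% of the 1 Mb bins of chromosome 16 lie within 10 points. No technical explanation was tested for this region.

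H3K4me3 peaks without H3K27ac had low scores, and a candidate explanation is that H3K27ac at these sites lay just under the calling threshold. Of the 1222 H3K27ac peaks that met an H3K4me3 peak scoring under 100, 17.5% (interval 15.4 to 19.8%) scored under 200, compared with 10.6% of the H3K27ac peaks that met any H3K4me3 peak and 30.1% of all H3K27ac peaks. This does not decide the question, although a share under 25% had been set beforehand as evidence against a near miss. The limit was wrong because the measure covers only the 1251 weak H3K4me3 peaks where H3K27ac was called, and not the 919 where it was not. A near miss, false calls of H3K4me3, a difference in depth between the libraries and H3K4me3 without acetylation all stay open.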
